A study of Danio rerio with 8 samples.

How the data were processed

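Counts per gene were analysed for 8 RNA-seq libraries of GFP-positive cells sorted from zebrafish larvae at 96 hours post fertilization (hpf), 4 from larvae given a standard control morpholino and 4 from larvae given a morpholino against an exon-intron junction of hpse2. A morpholino is an antisense oligomer, here one that interferes with splicing of its target transcript. Per the labels' protocols, 60 to 80 larvae were pooled, of a line in which fli1a regulatory sequence drives GFP, the larvae were dissociated with trypsin, dead cells were excluded with propidium iodide, and an ultra-low-input protocol for polyadenylated RNA was used. In this line GFP marks the vascular endothelium and also cranial neural crest derivatives of the pharyngeal arches.

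The deposited values are raw read counts per gene in 1 table of 32520 genes, with Ensembl gene identifiers, names and coordinates. The genome build was GRCz11, per the submitters' processing notes. The aligner, the counting tool, their versions and the use of strand are not given in the sources used here. No value shows whether reads shared between paralogs were dropped or assigned, so values of duplicated genes with near-identical sequence are uncertain. The gene length that accompanies the deposited counts served only to describe hpse2. Each column was assigned to a sample through the sample's description, and 0 sample columns were left unassigned.

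Genes with too few counts were removed with filterByExpr, which left 15559 genes. Library sizes were scaled by trimmed means (TMM), and the groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersions, without a replicate block, and with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Levels of single genes are CPM, counts divided by the TMM-scaled library size and brought to a common total, log2 CPM values carry a prior count of 2, and fold changes are log2 values of the LOF-labelled libraries minus the controls. Standard errors (SE) of fold changes were derived from the fold change and its F statistic.

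The design, the alternatives and 41 gene lists with 1189 entries were fixed before the data were examined. Of the entries, 1137 matched a gene name in the table, 11 matched through a table of gene names and 41 did not match. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 41 lists, and again with an estimated correlation and with fry. For each list the CPM of its members was also summed per library on the unscaled total, and log2 sums were compared with exact two-sided permutation tests, in which 4 against 4 libraries give 70 arrangements and a smallest p of 0.0286. These tests treat the 8 libraries as independent, although the 2 libraries of a biological replicate are not. The lists were neural crest and cartilage; photoreceptors and lens; neurons; Wnt targets; neutrophils; fibroblast; unfolded protein and integrated stress response; cell cycle; mural cells; dissociation and immediate early genes; basement membrane; VEGF ligands and receptors; liver; skeletal and cardiac muscle; glycolysis; integrins; heparan sulfate proteoglycan cores; erythrocytes; thrombocytes; epidermis; matrix proteases and inhibitors; Notch targets; endothelial junctions and permeability; flow responsive factors; glia and neural progenitors; BMP and TGF-beta targets; FGF signalling; heparan sulfate synthesis and modification; arterial endothelium; inflammation and leukocyte adhesion; endothelial identity; cholesterol synthesis; intestine; macrophages; mitochondrial genome; p53 response; coagulation and haemostasis; interferon response; hyaluronan and other glycocalyx; exocrine pancreas; venous and lymphatic endothelium.

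The genes named in the text follow a rule: hpse2, then called genes with non-overlapping groups and a mean log2 CPM of at least 1 that have a standard name, up to 8 per direction by fold change, then up to 4 called members of each pathway or cell type list or the 2 members of smallest p where none was called, and the 2 most abundant members of each list of another cell type. Where fewer than 5 genes passed in a direction, the 5 with the smallest p are given as values. All called genes are named, and any other gene named, list members included, was chosen after its value was seen.

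The alternatives were other scaling factors, other low-count filters, DESeq2 1.42.0, limma-voom with and without sample weights, 3 replicate blocks, sums per biological replicate, biological replicate as a random effect, 1 surrogate variable (sva 3.50.0), a fold limit of 1.5, another prior count of 0.5 for the list tests, and the omission of each library in turn. A crossed replicate block was added after the data were seen. On simulated counts for the 15559 genes of this comparison, the edgeR test recovered 15.4% of 201 genes changed 1.5-fold, 57.2% of 201 changed 2-fold and 89.4% of 198 changed 4-fold, and called 0.0509% of the unchanged genes. The simulated libraries were independent, without replicate pairs or library sets, so these rates need not hold for the real libraries. Total counts ranged from 5048839 to 11344918 per library, so that 3 counts correspond to 0.594 CPM in the shallowest library and 0.264 CPM in the deepest. Intervals made from counts cover counting error only, since reads without molecular identifiers are not independent molecules.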

Results

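Gene expression was measured by RNA-seq in GFP-positive cells sorted from 96 hpf zebrafish larvae, in 4 control libraries and 4 libraries labelled Hpa2 loss-of-function, called LOF-labelled libraries from here on. Each group holds 2 biological replicates with 2 libraries each, numbered 1_1, 1_2, 2_1 and 2_2. The control libraries held 8666356, 5048839, 7718334 and 11344918 counts in that order, and the LOF-labelled libraries held 7828120, 9475118, 7552963 and 7504508. The labels do not say whether the 2 libraries of a biological replicate came from separate pools of larvae. They were not independent, with a correlation of 0.50 within biological replicates in the random-effect fit. Tests on 4 against 4 libraries may in part measure technical spread, and their p-values and SEs can be too small. The chi-square per gene was 2.56 to 5.80 between the 2 libraries of a biological replicate and 13.7 to 24.2 between biological replicates of a group, so no 2 libraries agreed within sampling noise.

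The sorted cells held abundant transcripts of cartilage and connective tissue beside those of endothelium. The summed level of 33 endothelial identity genes was 1448 ± 281 CPM in the controls and 1427 ± 168 CPM in the LOF-labelled libraries (mean ± SD, n = 4). The 39 neural crest and cartilage genes summed to 41479 ± 1135 CPM in the controls and 29878 ± 5941 CPM in the LOF-labelled libraries, and the 27 fibroblast genes to 46209 ± 3917 CPM in the controls and 53706 ± 6108 CPM in the LOF-labelled libraries. Epidermal genes summed to 3212 CPM in the controls and erythrocyte genes to 1905 CPM. Much of the epidermal sum was pfn1, at 2075 CPM in the controls.

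The first principal component held 40.3% of the variance and did not separate the groups. It placed control 1_1 and 1_2 with LOF-labelled 2_1 and 2_2, called the first library set here, and control 2_1 and 2_2 with LOF-labelled 1_1 and 1_2, the second set. Each set holds 2 libraries of each group, so group differences are also given within the sets.

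**Figure D1:**
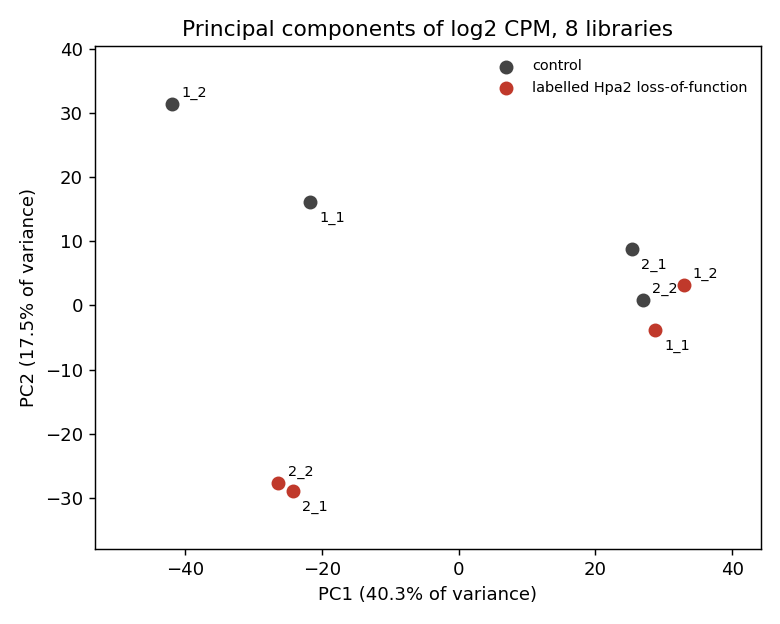
Principal components of log2 CPM over 15559 genes, with PC1 on the horizontal and PC2 on the vertical axis (component scores, share of variance in percent), 1 point per library, numbered by replicate. PC1, with 40.3% of the variance, parts the 4 libraries of the first set from the 4 of the second set, and each set holds both groups.

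The morpholino's target, hpse2, encodes heparanase 2, a relative of heparanase that binds heparan sulfate and lacks its enzyme activity. It lies on the forward strand of chromosome 13, 40501455 to 40668077 (GRCz11, identifier ENSDARG00000078163), and its counted length was 1683 bases. Its level was 28.5 ± 5.78 CPM in the controls and 65.8 ± 20.3 CPM in the LOF-labelled libraries (mean ± SD, n = 4), a log2 fold change of 1.198 (SE 0.23). Counts were 232, 98, 259 and 385 in controls 1_1, 1_2, 2_1 and 2_2, and 659, 801, 358 and 364 in the LOF-labelled libraries of the same numbers. All 4 LOF-labelled libraries lay above all 4 controls (exact two-sided permutation p = 0.0286, the smallest that 70 arrangements can give), with differences of 1.00 in the first set and 1.34 in the second. The edgeR test over all genes did not call hpse2 (adjusted p = 0.130), whereas DESeq2 did at a log2 fold change of 1.21, and edgeR did with the library sets as a block, chosen after the data were seen (adjusted p = 4.15e-07), but not with counts summed per biological replicate, where no gene was called. The gene count was not lower under the label, and a morpholino at a splice junction need not lower it, so these counts do not check the loss of function.

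The comparison of the groups asks how loss of Hpa2 affects gene expression in the sorted cells. Aggrecan (acana), the large proteoglycan of cartilage, fell from 313 ± 14.02 to 147 ± 21.3 CPM, and the cartilage matrix protein matrilin 1 (matn1) fell from 5319 ± 861 to 2250.3 ± 539 CPM (mean ± SD, n = 4). The neural crest transcription factor sox10 and csgalnact1a, an enzyme that starts and extends chondroitin sulfate chains, were also called. Of 15559 genes, 14 were called, 13 lower and 1 higher. All 14 had the same direction in both library sets, as did 965 of the 978 genes at an unadjusted p under 0.05. The sets are parts of the same libraries, so this agreement is no independent support. Counts summed per biological replicate gave 0 calls, and biological replicate as a random effect gave 2. The balance of higher and lower genes differed among the alternatives that call more genes. Lower genes prevailed with DESeq2 (21 higher, 74 lower), sample weights (7 higher, 63 lower) and no low-count filter (4 higher, 28 lower). The balance was 175 higher and 221 lower when the library sets were a block and 212 higher and 225 lower with 1 surrogate variable. That variable follows the library sets, so these 2 fits are not separate evidence.

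The log2 fold change was -1.09 (SE 0.11, adjusted p = 0.0143) for acana (chromosome 7, 48761646 to 48787379), -1.24 (SE 0.18, adjusted p = 0.0410) for matn1 (chromosome 19, 43314700 to 43338280), -0.97 (SE 0.14, adjusted p = 0.0410) for sox10 (chromosome 3, 1492174 to 1501255) and -0.9999 (SE 0.12, adjusted p = 0.0162) for csgalnact1a (chromosome 10, 8298984 to 8358396). Tenascin XB (tnxba) fell by 1.31 on the log2 scale, the procollagen processing enhancer pcolceb by 1.32, and cthrc1b, a secreted protein with a collagen repeat, by 0.85. The hyaluronan-binding inter-alpha-trypsin inhibitor heavy chain itih1 fell by 1.04 and melanotransferrin (meltf) by 1.07. The transcription factor genes foxa3 and mybl1 had log2 fold changes of -1.31 and -0.74, and the unnamed gene ENSDARG00000110756 had -1.59. The SEs of these 8 genes lay between 0.11 and 0.19 and their adjusted p between 0.0162 and 0.0485.

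The gene thoc6, of an mRNA export complex, was called at low counts, 1 to 4 per LOF-labelled library against 11 to 63 per control library. The ratio of its summed counts, 9 against 136, was 0.0670 after division by the total counts (95% exact interval 0.0300 to 0.131, counting error only). The called higher gene was zgc:153704 (chromosome 5, 4482437 to 4493524), which rose from 154 ± 20.2 to 256 ± 18.8 CPM, a log2 fold change of 0.73 (SE 0.11, adjusted p = 0.0476). The next smallest p among higher genes belonged to nr1d2a, a nuclear receptor of the circadian clock (0.57), CR753876.1 (0.70), the transcription factor cebpd (0.52) and the stress-induced mTOR inhibitor ddit4 (0.88), with adjusted p of 0.0716 to 0.106.

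**Figure D2:**
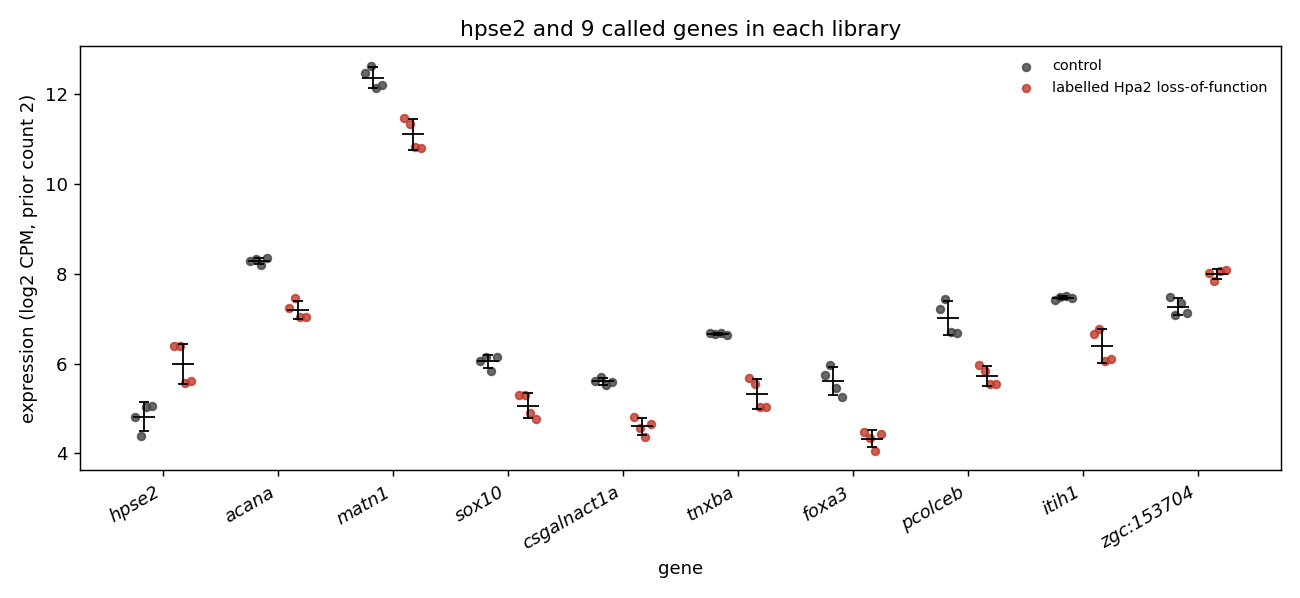
Expression in log2 CPM (vertical axis, prior count 2) of hpse2 and 9 called genes (horizontal axis), with 1 point per library, control and LOF-labelled libraries side by side, and the mean ± SD of 4 libraries as a bar. For each gene the 4 points of one group lie apart from the 4 of the other, and hpse2 and zgc:153704 are the genes drawn with higher LOF-labelled values.

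No gene was called by edgeR without control 1_1, LOF-labelled 2_1 or LOF-labelled 2_2 (854, 892 and 970 genes at an unadjusted p under 0.05), and 5, 8, 6 and 3 genes were called without control 1_2, control 2_1, control 2_2 and LOF-labelled 1_1. The 14 genes kept their direction in every alternative, all of which reuse the same libraries. Counts summed per biological replicate (2 against 2) gave 0 calls (299 genes at an unadjusted p under 0.05), DESeq2 gave 95 and a block for the library sets 396. That block was chosen after the data were seen. Since each set holds 1 biological replicate per group, its spread is mostly between the 2 libraries of a biological replicate. It kept 13 of the 14 calls and lost matn1 (-1.26, adjusted p = 0.0506). Beside hpse2 it added calls for the named genes papss2b, col15a1b, nr1d2a, ext1c, CR753876.1, cebpd, ddit4, fgfr3, rbp4, cdkn1a, f13a1b, thbs1b, gadd45bb, spock2, has3, col2a1a, fn1b, gpc6a, tubb5, glula, rhag, pdia4, socs3a, mmp25b, klf2b, mpx, klf9, cpa5, npsn, hyal4, sox7 and mrc1a.

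Among the 41 gene lists, neural crest and cartilage genes had the smallest p. Of 34 members tested, 3 fell and 31 did not pass the test over all genes, and 16 lower and 1 higher members passed when adjusted over the list alone. Beside acana, matn1 and sox10, the lower members that passed only within the list included the cartilage collagen col11a2 (-0.92), the link protein hapln1b (-1.01), the second aggrecan acanb (-1.31) and col2a1a (-0.44), and the higher one was ucmaa (0.64). The other abundant type II collagen gene, col2a1b, was at -0.29. The list's median log2 fold change was -0.25 (camera adjusted p = 1.44e-09), -0.49 in the first library set and -0.13 in the second. The call was lost with an estimated correlation (adjusted p = 0.957) and with fry (adjusted p = 0.658). The median was nearer to 0 without LOF-labelled 2_1 (-0.16) or LOF-labelled 2_2 (-0.16), where the call held. With the library sets as a block the list's median was -0.26 (camera adjusted p = 3.60e-06). The list's summed level differed by -0.49 on the log2 scale (exact permutation p = 0.0286, the smallest possible, adjusted over 15 lists of other cell types 0.143).

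**Figure D3:**
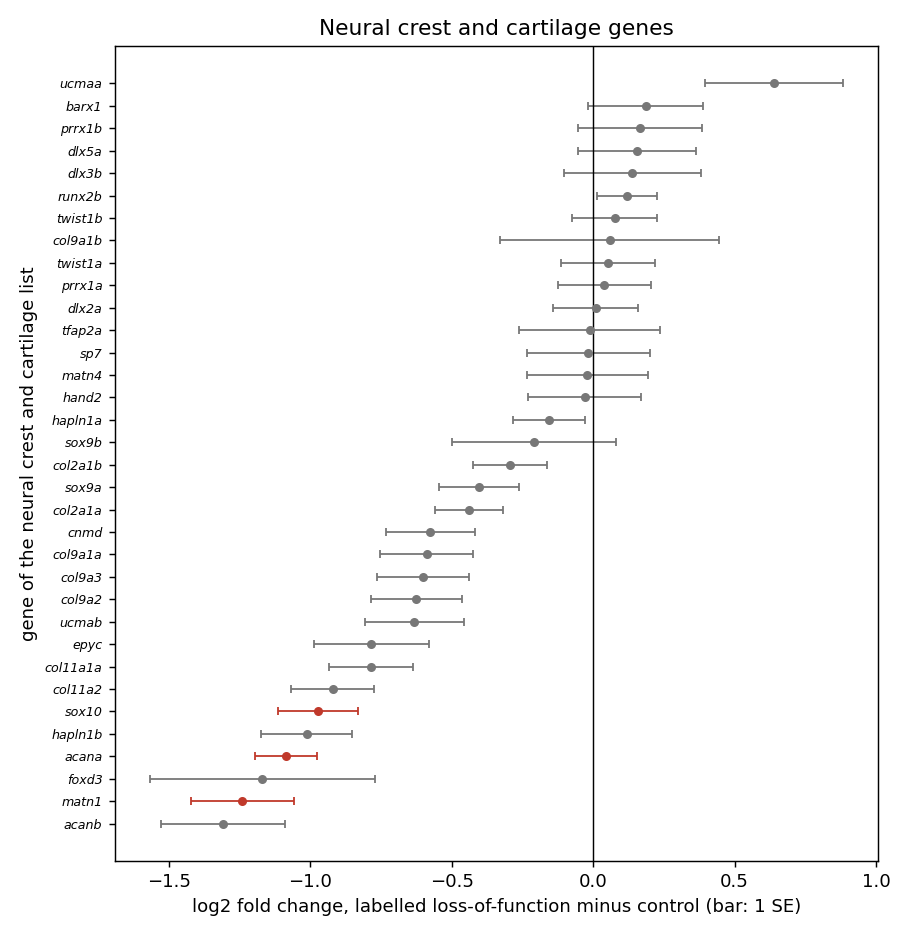
Log2 fold change, LOF-labelled minus control (horizontal axis, bars 1 SE), of the 34 tested neural crest and cartilage genes (vertical axis), with genes called over all 15559 genes in red. Values run from -1.31 for acanb to 0.64 for ucmaa.

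Lists of other cell types were also called by camera. Photoreceptor and lens genes were lower (median -1.11, adjusted p = 2.00e-05, or adjusted p = 0.957 with an estimated correlation), with all 16 members below 0, among them the opsin opn1mw1 at -1.65 and rho at -0.69, and their summed level was 409 ± 354 CPM in the controls and 205 ± 70.5 CPM in the LOF-labelled libraries. Control 1_1 held opn1mw1 at 153 CPM against 20.5 to 53.8 CPM in the other controls, and without it the values were -0.69 for opn1mw1, -0.013 for rho and -0.69 for the list's median. The median of this list was -1.87 in the first library set and -0.19 in the second. Its sum was 833 and 570 CPM in controls 1_1 and 1_2 but 123 and 112 CPM in controls 2_1 and 2_2. In the second set the LOF-labelled sums, 142 and 145 CPM, lay above those of the controls. Neuronal genes were lower (median -0.27, adjusted p = 4.59e-05, or adjusted p = 0.957 with an estimated correlation), with 28 of 31 members below 0, tubb5 at -0.27 and atp1a3a at -0.26, as were neutrophil genes (median -0.38, adjusted p = 0.00191, or adjusted p = 0.957 with an estimated correlation), with the granule genes mpx at -0.38 and npsn at -0.46. Fibroblast genes were higher (median 0.17, adjusted p = 0.00486, or adjusted p = 0.957 with an estimated correlation), with 21 of 24 above 0, col1a1b at 0.25 and col1a2 at 0.22, while the 1 called member, tnxba, fell. Mural cell genes, of pericytes and smooth muscle, were higher (median 0.20, adjusted p = 0.0248, or adjusted p = 0.957 with an estimated correlation), with pdgfrb at 0.12 and foxc1b at -0.034. In the main test no member of the photoreceptor, neuron, neutrophil or mural lists passed over all genes. The summed level of neuronal genes was 696 ± 72.9 CPM in the controls and 604 ± 14.6 CPM in the LOF-labelled libraries (exact permutation p = 0.0286, adjusted over the 15 lists of other cell types 0.143). Leaving out 1 library ended the neutrophil call without control 1_2 (-0.16) or LOF-labelled 1_2 (-0.19), the fibroblast call without control 1_2 (0.097), LOF-labelled 1_1 (0.10) or LOF-labelled 1_2 (0.098) and the mural call without control 1_2 (0.067), LOF-labelled 1_1 (0.077) or LOF-labelled 1_2 (0.069), with the median of each list in parentheses. The median moved by over 1.5 times with the call kept for neurons without control 1_1 (-0.11) and for mural cells without control 1_1 (0.13), LOF-labelled 2_1 (0.31) or LOF-labelled 2_2 (0.30).

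Among pathway lists, Wnt targets were higher (median 0.20, adjusted p = 0.00132, or adjusted p = 0.957 with an estimated correlation). All 11 tested Wnt targets had positive values, among them notum1a (0.33) and apcdd1l (0.37), and no single one was called. Basement membrane genes were higher (median 0.11, adjusted p = 0.0361, or adjusted p = 0.957 with an estimated correlation), with fn1b at 0.38, although the member of smallest p, the collagen col15a1b, was lower (-0.76, adjusted p = 0.0716). The dissociation and immediate early list was higher (median 0.032, adjusted p = 0.0340, or adjusted p = 0.957 with an estimated correlation), with cebpd and socs3a (0.54) leading, and its median was -0.019 in the first library set. The summed level of this list was 29327 to 30293 CPM in the first library set and 18826 to 21576 CPM in the second. Genes of the unfolded protein and integrated stress response were lower (median -0.18, adjusted p = 0.00513, or adjusted p = 0.957 with an estimated correlation), with the chaperone pdia4 at -0.25 and ddit4 in the other direction, and cell cycle genes were lower (median -0.060, adjusted p = 0.0214, or adjusted p = 0.957 with an estimated correlation), with ccnb1 at -0.22 and ccne1 at 1.40. Leaving out 1 library ended the basement membrane call without control 1_2 (0.055), control 2_1 (0.13), LOF-labelled 1_1 (0.097) or LOF-labelled 1_2 (0.049), the stress response call without control 1_2 (-0.095), LOF-labelled 1_1 (-0.12) or LOF-labelled 1_2 (-0.16), the cell cycle call without control 1_2 (-0.015), LOF-labelled 1_1 (-0.036) or LOF-labelled 1_2 (-0.049) and the dissociation call without control 2_1 (-0.097), control 2_2 (-0.081), LOF-labelled 2_1 (-0.039) or LOF-labelled 2_2 (-0.053), where its median lay below 0. The median moved by over 1.5 times with the call kept for cell cycle genes without control 2_1 (-0.10), control 2_2 (-0.093), LOF-labelled 2_1 (-0.091) or LOF-labelled 2_2 (-0.10) and for dissociation genes without control 1_1 (0.14), control 1_2 (0.21), LOF-labelled 1_1 (0.12) or LOF-labelled 1_2 (0.13). No list was called by fry, which asks whether a list moves on balance in one direction, and its mixed test, which asks whether members change in either direction, called 6 lists, neural crest and cartilage, fibroblast, thrombocytes, glia and neural progenitors, heparan sulfate synthesis and modification and p53 response.

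Genes of heparan sulfate metabolism were not called as a list (median 0.033 over 33 members, camera adjusted p = 0.702), except with sample weights (-0.065), whereas fry's mixed test called it (adjusted p = 0.00134). No member passed over all genes in the main test, while 3 lower and 2 higher members passed when adjusted over the list alone, hpse2 among the latter. The 2 of smallest p were papss2b, which makes the sulfate donor, at -0.59 (SE 0.096, adjusted p = 0.0618) and ext1c, of the heparan sulfate polymerase, at -0.94 (SE 0.16, adjusted p = 0.0716). With the library sets as a block, chosen after the data were seen, papss2b (adjusted p = 5.56e-06), ext1c (adjusted p = 3.31e-04) and hpse2 were called by edgeR over all genes. The spread in that fit is mostly between the 2 libraries of a biological replicate, and counts summed per biological replicate gave 0 calls. The proteoglycan cores had a median of 0.070, with spock2 at -0.86 and gpc6a at 0.41, and hyaluronan and other glycocalyx genes -0.0051, with has3 at -0.99 and hyal4 at 0.29. In each of these lists 1 lower member, spock2 and has3, passed when adjusted over the list alone.

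Endothelial and growth factor lists were not called in the main test, where none of their members passed over all genes. With the block for the library sets fgfr3, klf9, mrc1a, sox7 and klf2b did. The median was -0.021 for endothelial identity, with sox7 at -0.40 and esama at -0.29, and 0.016 for 41 junction and permeability genes, with jupb at 0.49 and tjp1b at 0.17. VEGF ligands and receptors had a median of 0.13 (adjusted p = 0.0537), with vegfaa at 0.16 and nrp2a at 0.14. The VEGF list was called in 7 of 25 alternatives, with the description number block (0.14), 1 surrogate variable (0.10) and the block for the library sets (0.13), and without control 2_1 (0.16), control 2_2 (0.20), LOF-labelled 2_1 (0.17) or LOF-labelled 2_2 (0.20), with the list's median in parentheses here and for the lists below. Endothelial identity was called in 2 of 25 alternatives, with sample weights (-0.23) and 1 surrogate variable (-0.050). FGF signalling had a median of 0.061, and its member of smallest p, the receptor fgfr3 (-0.61, adjusted p = 0.108), passed when adjusted over the list alone, with etv5a at -1.03. Arterial genes had a median of -0.14, with tbx20 at -0.82 and unc5b at 0.25. Venous and lymphatic genes had -0.0039, with mrc1a at -0.40 and lyve1b at -1.55. Notch targets had -0.074, with hey2 at -0.27 and her4.1 at -0.51, and BMP and TGF-beta targets had 0.055, with bmpr2b at 0.22 and skila at 0.19. Flow responsive factors had 0.053 (mean log2 difference 0.096, exact permutation p = 0.0286, unadjusted), with klf2b at -0.31 and klf9 at 0.70, and integrins had 0.10, with itgb5 at 0.33 and itga8 at 0.23.

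The remaining pathway lists were not called by camera in the main test either. The p53 response had a median of -0.034, and 3 higher members, cdkn1a (0.47), gadd45bb (0.34) and sesn1, passed when adjusted over the list alone. Coagulation genes had 0.033, with f13a1b at -0.46, the 1 member that passed within the list, and f3a at 0.52. Summed levels of p53 response genes were 2616 ± 104 CPM in the controls and 2877 ± 94.1 CPM in the LOF-labelled libraries, a log2 difference of 0.14, and those of coagulation genes were 1664 ± 128 CPM in the controls and 1401 ± 71.7 CPM in the LOF-labelled libraries, a difference of -0.25. Both sums had the smallest exact permutation p of 0.0286, as did those of 3 lists of other cell types, and 0.234 when adjusted over all 41 list sums. Much of the fall of the coagulation sum was f13a1b, at 652 CPM in the controls and 472 CPM in the LOF-labelled libraries. Inflammation genes had -0.019, with nfkbiab at 0.19 and il11b at 0.89. Interferon response genes had -0.093, with socs1a at 0.44 and tap1 at -0.35, and matrix proteases and inhibitors 0.10, with mmp9 at -0.46 and mmp25b at -0.59. Glycolysis genes had -0.20, with hk2 at -0.37 and pfkpa at -0.31, and cholesterol synthesis genes 0.012, with acat2 at -0.23 and stard4 at 0.42. Mitochondrial genes had a median of -0.060. The glycolysis list was called in 5 of 25 alternatives, with 1 surrogate variable (-0.14) and the block for the library sets (-0.18), and without control 2_1 (-0.30), control 2_2 (-0.32) or LOF-labelled 2_1 (-0.19). The inflammation list was called with sample weights (0.43).

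Of the other cell types not called in the main test, liver genes had a median of 0.0050, and 3 higher members, rbp4 (0.50), tfa (0.46) and fetub, passed when adjusted over the list alone. Their summed level was 304 ± 30.0 CPM in the controls and 428 ± 29.1 CPM in the LOF-labelled libraries, a log2 difference of 0.50 (exact permutation p = 0.0286, the smallest possible, adjusted over 15 lists 0.143), and their median ranged from -0.19 to 0.54 when 1 library was left out. The median was 0.30 for erythrocytes (rhag 0.26, slc4a1a 0.099), -0.085 for thrombocytes (thbs1b -0.54, fn1b 0.38) and 0.19 for macrophages (lcp1 -0.12, laptm5 0.091). Epidermal genes had 0.072 (krt8 0.050, pfn1 -0.077), glia and neural progenitors -0.0081 (glula 0.30, cx43 0.13) and skeletal and cardiac muscle 0.0077 (actc1b -0.21, tpm1 0.16). Muscle genes differed in opposite directions in the library sets, with medians of -3.23 and 1.43. In the second set their sum was 4053 CPM in LOF-labelled 1_2 but 1023 CPM in LOF-labelled 1_1, beside 1098 and 727 CPM in controls 2_1 and 2_2. Intestinal genes had -0.033 (dab2 -0.25, apoa1b 0.38) and exocrine pancreas genes -0.00048 (cpa5 -0.41, pdia2 -0.00048). Adjusted over the list alone, 2 lower and 1 higher thrombocyte genes, 2 lower and 1 higher glial genes and 1 higher epidermal gene passed. Erythrocyte genes were called in 6 of 25 alternatives, with sample weights (0.73), 1 surrogate variable (0.31) and the block for the library sets (0.20), and without control 1_2 (0.48), LOF-labelled 1_1 (0.51) or LOF-labelled 1_2 (0.48). Muscle genes were called in 8 of 25 alternatives, with the CPM filter (-0.089), sample weights (-1.57), the biological replicate number block (-0.34) and the full number block (-0.74), and without control 2_1 (-0.22), control 2_2 (-0.30), LOF-labelled 1_1 (-0.0088) or LOF-labelled 1_2 (-1.46). Liver genes were called in 4 of 25 alternatives, with sample weights (0.49) and without control 1_1 (0.54), control 1_2 (0.22) or LOF-labelled 1_1 (0.19). Macrophage genes were called in 2 of 25 alternatives, with sample weights (0.55) and without LOF-labelled 1_2 (0.46). The camera direction and the median had opposite signs for muscle, heparan sulfate synthesis, inflammation, intestine, p53 response, exocrine pancreas and venous and lymphatic genes. The summed level and the median had opposite signs for BMP and TGF-beta targets, coagulation and haemostasis, epidermis, flow responsive factors, glia and neural progenitors, heparan sulfate synthesis and modification, hyaluronan and other glycocalyx, inflammation and leukocyte adhesion, interferon response, intestine, macrophages, p53 response, skeletal and cardiac muscle and venous and lymphatic endothelium. The mean log2 level and the median had opposite signs for exocrine pancreas, heparan sulfate synthesis and modification, inflammation and leukocyte adhesion, intestine and skeletal and cardiac muscle. At an unadjusted p under 0.05 there were 978 genes, 460 higher and 518 lower, and the groups did not overlap for 723 genes, 4.65% against 2.86% by chance if the 8 libraries were independent. The 2 libraries of a biological replicate are not, and the library sets cut across the groups. The chance share for such libraries was not calculated, so no excess over chance is shown.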

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

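The tests on library depth and on clock genes were chosen before their results were seen, and the tests of splits, of hpse2, of replicate numbers and of the cartilage genes' common fold change and values within the sets were chosen only after. Libraries far from the other 3 of their group were sought in 282 groups of 4 values, and 7 were found. Chance gives about 1 in 20 for independent values, a larger share than was found, so the 7 show no excess. The 4 values of a group come from 2 biological replicates, so that rate need not hold here. In the LOF-labelled libraries rhag was highest in 2_1, at 577 CPM against 562 to 564 in the others, and stard4 was highest in 2_1, at 7.42 CPM against 5.18 to 5.51. In LOF-labelled 1_1 apoa1b was lowest at 4.68 CPM against 10.5 to 10.7. In the controls socs3a was highest in 1_1 at 523 CPM against 319 to 344, and apcdd1l was lowest in 1_2 at 23.7 CPM against 32.4 to 34.3. The neural crest and cartilage sum was lowest in control 2_1, at 39780.1 CPM against 41984 to 42160.0. Mitochondrial rRNA was lowest in LOF-labelled 1_2, at 1.02% of counts against 1.17% in each of the others.

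Chance cannot be excluded for the 14 called genes. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least 14, a share of 0.0571, and the highest other split gave 3960. That split follows the 2 library sets and points to a structure of the samples, and the highest of the splits that follow neither the groups nor the sets gave 2. A fit with the sets as a block called 396 genes.

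The first pattern is the lower cartilage genes in the LOF-labelled libraries. Thinning each library to 5048839 counts left the list's median at -0.31, against -0.25 with all counts. Thinning keeps each gene's expected share of its library, so the median was likely to stay in any case and cannot decide on depth. The median stayed below 0 in both library sets, at -0.13 in the set nearer to 0. A lower share of all neural crest and cartilage cells alike would lower by the same amount only members that no other sorted cells express. The weighted sum of squares of the members around their common fold change was 7.92 per degree of freedom. Members also expressed in other cells would fall less, and the SEs used treat the libraries as independent, so this value cannot decide. A lower share of all these cells or of a kind of them, such as chondrocytes, and lower expression per cell stay open. So does an effect of the hpse2 morpholino, which was not tested apart from the group label.

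The second pattern is the higher hpse2 count. No gene of the table overlaps hpse2, and the highest fold change of its tested neighbours within 50000 bases was -0.0064. These values argue against reads of overlapping genes and of the tested neighbours. The neighbour st3gal7 was not tested, and reads shared with paralogs were not examined. A larger share of a listed type as a whole would raise markers confined to that type by at least as much as hpse2. The highest median among 18 cell type lists was 0.30, but members also expressed in other cells would rise less, so the medians cannot decide. In the second set the muscle and exocrine pancreas medians were 1.43 and 1.37 beside 1.34 for hpse2. In the first they were -3.23 and -0.48 beside 1.00. The second-set muscle sum was 4053 CPM in LOF-labelled 1_2 but 1023 CPM in LOF-labelled 1_1, beside 1098 and 727 CPM in the controls. The pancreas sum was 213 CPM in LOF-labelled 1_1 but 106 CPM in LOF-labelled 1_2, beside 159 and 141 CPM in the controls. A larger share of a listed type, of a kind of cell within a list or of types outside the lists stays open. An exchange of the group labels cannot be told apart from a splice change with a higher count, at a log2 fold change of 1.198, because gene counts hold no splice junctions. A higher hpse2 count after splice blocking stays an untested biological explanation.

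The third pattern is the pair of library sets. Thinning to equal totals left 3274 genes called between the sets, against 3960 with all counts. The calls that remained do not need unequal totals, but thinning keeps expected shares. Differences in shares that go with depth would remain, so depth is not decided. An exchange of biological replicate numbers in one group cannot be told apart from numbers that mark no shared batch: 4 of the 4 controls correlated best with a LOF-labelled library of the other number, but the sets were seen in the same correlations. Time of day or light before collection stays open: per2, a light-induced clock gene, was at 7.19 log2 CPM in the first set and 3.88 in the second, and among 30 clock genes whose values had not been looked at, 12 (40%) were called between the sets against 25.4% of other genes (Fisher's exact one-sided p = 0.0569). The bound of 0.05 set beforehand was missed, which does not decide, since the share was higher as predicted and a missed p excludes nothing. The test also treats the 30 clock genes as independent. They may move together, so its p can be too small. Sample handling and cell composition were not tested apart from the sets and stay open, as does any biological explanation: 25 of 41 list sums lay apart between the sets, among them dissociation and immediate early genes at 29327 to 30293 CPM in the first library set and 18826 to 21576 CPM in the second, glycolysis at 3194 to 3951 CPM in the first library set and 2231 to 2556 CPM in the second and erythrocytes at 2344 to 3552 CPM in the first library set and 1227 to 1378 CPM in the second.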

How the results depend on the processing

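All alternatives below were planned except the crossed block. The 14 called genes kept their direction in all alternatives, which reuse the same libraries, and of their alternative values 184 stayed past the threshold and 152 did not. The 11 called lists kept their camera direction in all alternatives, with 212 values past the threshold and 63 not. Their medians did not all keep their sign: that of dissociation genes turned without control 2_1, control 2_2, LOF-labelled 2_1 or LOF-labelled 2_2, and with sample weights those of mural (-0.083) and cell cycle genes (0.012) turned, with neither list called. Without single libraries the medians of the called lists ranged from -0.36 to -0.16 for neural crest and cartilage, -1.35 to -0.69 for photoreceptors and lens, -0.34 to -0.11 for neurons, 0.16 to 0.28 for Wnt targets, -0.46 to -0.16 for neutrophils, 0.097 to 0.20 for fibroblast, -0.17 to -0.095 for unfolded protein and integrated stress response, -0.10 to -0.015 for cell cycle, 0.067 to 0.31 for mural cells, -0.097 to 0.21 for dissociation and immediate early genes and 0.049 to 0.17 for basement membrane. For the counts below the cause was not tested, except that leaving out or summing libraries leaves fewer samples. The surrogate variable follows the library sets, as given below. The number of called genes was 13 to 14 under the other scalings, the CPM filter and limma-voom. It was 32 without a low-count filter (4 higher, 28 lower), 95 with DESeq2 (21 higher, 74 lower) and 70 with limma-voom and sample weights (7 higher, 63 lower). It was 437 with 1 surrogate variable (212 higher, 225 lower), 2 with biological replicate as a random effect (0 higher, 2 lower), 0 (0 higher, 0 lower) with sums per biological replicate in edgeR and 0 (0 higher, 0 lower) with a fold limit of 1.5, where 299 and 134 genes had an unadjusted p under 0.05. Without each library in turn it was 0 to 20 (higher 0 to 1, lower 0 to 19): 0 without control 1_1, 5 without control 1_2, 8 without control 2_1, 6 without control 2_2, 3 without LOF-labelled 1_1, 20 without LOF-labelled 1_2, 0 without LOF-labelled 2_1 and 0 without LOF-labelled 2_2; the 3 counts of 0 stand beside 854, 892 and 970 genes at an unadjusted p under 0.05.

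The shared numbers of the titles do not pair the libraries: deviations from the group means correlated at -0.49 between libraries of the same biological replicate number, and none of the 4 controls correlated best with its own number. As a replicate block, the biological replicate number gave 17 called genes (0 higher, 17 lower), the full number 0 (0 higher, 0 lower, 524 at an unadjusted p under 0.05) and the number in the description 3 (0 higher, 3 lower). The negative correlation suggested crossed numbers, and the crossed replicate block, chosen after seeing the data, gave 396 called genes (175 higher, 221 lower). The hpse2 fold change ranged from 0.85 to 1.33 and passed the threshold with DESeq2 (1.21), 1 surrogate variable (1.13) and the crossed block (1.17). The surrogate variable ran from -0.50 to -0.27 in the first library set and from 0.31 to 0.39 in the second. It follows the sets, so its 437 calls and its hpse2 call are not separate from those of the crossed block. The same limit applies, a spread mostly between the 2 libraries of a biological replicate. Called lists numbered 0 to 15 over the 25 alternatives. The crossed block called 14, among them the 11 of the main test. Called lists numbered 11 with sample weights, of which 4 were among the 11, and 7 with sums per biological replicate. They numbered 0 with an estimated correlation, 0 with fry and 7 to 13 without single libraries (7 without control 1_2). Of the 15 other cell type sums, 3 reached the smallest exact p (cartilage, neurons, liver) and 0 did as means of log2 CPM.

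No called gene or list reversed, and the values that did reverse belong to genes and lists called neither in the main test nor under the setting named; lists are judged by the camera or fry direction and given as median log2 fold changes. The gene pdia2 reversed with DESeq2 size factors (0.0013), upper quartile factors (0.0081), no filter (0.0061) and the CPM filter (0.0073). Without a filter hyaluronan and other glycocalyx (0.021) and coagulation (-0.10) reversed, and with the CPM filter exocrine pancreas (-0.20). With sample weights the genes tpm1 (-0.049), pdgfrb (-0.018), rho (0.73), lcp1 (0.19), krt8 (-0.15), pfn1 (0.28) and pdia2 (0.36) reversed, as did the lists heparan sulfate proteoglycan cores (0.0020), FGF signalling (-0.041), endothelial junctions and permeability (-0.096), venous and lymphatic endothelium (-0.17), Notch targets (0.13), BMP and TGF-beta targets (-0.064), matrix proteases and inhibitors (-0.035), coagulation and haemostasis (0.0047), interferon response (0.15) and glycolysis (0.0095). Venous and lymphatic genes reversed under the biological replicate block (-0.026), the full number block (-0.016) and 1 surrogate variable (-0.070), interferon response with 1 surrogate variable (-0.025), p53 response under the description number block (-0.049) and exocrine pancreas under the crossed block (0.11).

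Without single libraries, the reversing genes ranged from -0.25 to 0.057 for lcp1, -0.053 to 0.15 for krt8, -0.11 to 0.29 for laptm5, -0.27 to 0.13 for pfn1, -0.16 to 0.40 for slc4a1a, -2.24 to 0.21 for actc1b, -0.19 to 0.091 for foxc1b and -0.24 to 0.22 for pdia2. The medians of the reversing lists ranged from -0.063 to 0.083 for heparan sulfate synthesis and modification, -0.17 to 0.075 for hyaluronan and other glycocalyx, -0.026 to 0.12 for FGF signalling, -0.047 to 0.12 for endothelial junctions and permeability, -0.15 to 0.086 for endothelial identity, -0.24 to -0.034 for arterial endothelium, -0.14 to 0.17 for venous and lymphatic endothelium, -0.23 to 0.10 for Notch targets, -0.019 to 0.10 for BMP and TGF-beta targets, -0.063 to 0.069 for coagulation and haemostasis, -0.21 to 0.21 for inflammation and leukocyte adhesion, -0.19 to 0.15 for interferon response, -0.058 to 0.023 for p53 response, -0.057 to 0.067 for cholesterol synthesis, -0.013 to 0.51 for erythrocytes, -0.11 to 0.46 for macrophages, -0.62 to 1.19 for exocrine pancreas and -0.098 to 0.025 for mitochondrial genome. The cause of these reversals was not tested. In simulated counts of independent libraries, without replicate pairs or library sets, the test recovered 15.4% of genes changed 1.5-fold. The rate for the paired libraries of this design was not simulated, and a gene that was not called may still differ.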

Other observations

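The comparison of clock genes between the library sets was chosen after the sets were seen. In the first set, control 1_1 and 1_2 with LOF-labelled 2_1 and 2_2, the cryptochromes cry5 and cry1a were at 3.87 and 7.38 log2 CPM, and in the second at 1.49 and 5.68. Of 37 clock and light genes tested with edgeR, 16 were called between the sets, among them cry2 (second minus first set -0.89) and nfil3-6 (-1.54), and nr1d4b was higher in the second set (0.54). Between the groups per2 differed by -0.096, per1a by 0.50 and nr1d1 by 0.68, and none of the 37 was called in the main test. The smallest adjusted p among them was that of nr1d2a (0.57, adjusted p = 0.0716 in edgeR). With the library sets as a block, chosen after the data were seen, edgeR called nr1d2a (0.56, adjusted p = 1.36e-05).

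A hypothesis arose from csgalnact1a, papss2b and the nucleotide sugar transporter slc35d1a (-0.64, adjusted p = 0.0618 in edgeR), which act in the synthesis or sulfation of chondroitin sulfate. Chondroitin sulfate synthesis genes as a group may be expressed at a lower level in the LOF-labelled libraries. The test was set before the values of its 22 genes were looked at, and it missed its bound of 0.05, which neither shows nor excludes the hypothesis, since the difference was in the predicted direction. Their mean log2 difference was -0.19 (exact two-sided permutation p = 0.114), 15 of the 22 were below 0, and none was called. The sulfate transporter slc26a2 (-0.49), csgalnact1b (-0.80) and chst11 (-0.40) had the smallest p among them. Cartilage is a main site of this synthesis, so the hypothesis is not independent of the lower cartilage genes.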
